A study of Mus musculus with 21 samples.

How the data were processed

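Hearts of mouse embryos were profiled by RNA-seq at E9.5 (5 flox and 5 null libraries) and E10.5 (3 and 3), and CHD4 binding by chromatin immunoprecipitation at E10.0 in 3 libraries. Per the labels, RNA libraries were polyadenylated and stranded, made from 200 ng of RNA at E9.5 and 300 ng at E10.5. The series text counts 2 biological and 3 technical replicates for the binding assay, so its 3 lists are not 3 independent samples. The 2 input libraries were not analysed here. Per the submitters' processing notes the tools were Bowtie 1.2.0, SAMtools 1.6, bedtools 2.25.0, HTSeq 0.6.2, DESeq2 1.6.3 and MACS2, on mm10.

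The RPKM values are the authors' deposited values, per kilobase of their gene length and per 1e6 reads of the library. The gene lengths in bp and the peak positions are also used as deposited by the authors. The strand setting of the counting is not stated, so overlapping antisense genes cannot be separated. Near-identical genes such as Hba-a1 and Hba-a2, and Eno1, which has processed copies, are uncertain. Hba-a1 and Hba-a2 held the same reads in nearly every library, so they are not independent members of the erythroid list. The authors' deposited log2 fold changes are of control over null, by DESeq2 per the submitters' processing notes, and may be shrunken. The p-values in the deposited tables are the authors' and adjusted by them, and only genes with an adjusted p of at most 0.05 are listed. The mean signal per gene and the test score in those deposited tables are the authors' DESeq2 values and were not used here. The peak score is a whole number that the authors deposited per library, and its scale is not stated.

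RPKM times gene length gave whole reads within 0.01 for 100% of values, so the depth of each library is known. Reads on listed genes were 14.6 to 20 M per library at E9.5 and 15 to 16.1 M at E10.5. Counts of reads limit precision for low genes, and this covers counting error only. Differences were fitted on log2(RPKM + 0.5), which understates changes of genes near 0.5 RPKM, for genes with a mean of at least 0.5 RPKM over the libraries of the stage. The fit was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), two-sided, each stage alone and with no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between stages was an interaction in 1 fit of all 16 libraries. Every adjusted p of a gene is limma's.

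For 21 gene lists camera was run with a preset correlation of 0.01 and with an estimated one, together with fry, adjusted over the lists with at least 3 measured genes. With the preset correlation camera also called lists in most other splits of the libraries, a median of 5 at E9.5 and 7 at E10.5. Calls within a list are given over all genes and adjusted over the list alone. For 12 paralog pairs the log2 ratio per library was compared by an exact permutation test, two-sided, adjusted over the pairs. Peaks were shared where they overlapped by at least 1 bp. The design called for peaks within 5 kb of a transcription start, but the gene table used (GRCm38.p6, the assembly of mm10) gives no strand, so peaks within 5 kb of either annotated gene end were counted. Coordinates were found for 99.7% of tested genes. Peak shares were compared with genes not called by Fisher's exact test, two-sided, and within 5 quintiles of mean expression over flox and null libraries.

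Groups, tests, lists, pairs, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule took, per stage, Chd4 and the 8 largest rises and 8 largest falls among called genes. These had no overlap between libraries, at least 1 RPKM in a group and a symbol that is no predicted model. It added up to 4 genes of smallest p per list, 4 and 4 genes of the stage difference, the 5 highest shared peaks, and peaks near called skeletal and smooth muscle genes. Genes outside it are said to be chosen after their values were seen. A few genes the rule returned are not reported here.

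These other settings were a pseudocount of 0.1 or 1, no filter or a mean of at least 1 RPKM, median scaling, quantile normalization, rescaling without erythroid and the 10 most abundant genes, arrayWeights, robust eBayes, a block by replicate number, and leaving out each library. For peaks they were windows of 1 and 50 kb, the upper part of peaks by score, single lists, a larger overlap and, for the authors' lists, an adjusted p under 0.1. Chosen after the data were seen were the sex of the library (by Xist against Ddx3y), the erythroid, epicardial and foregut and liver levels as covariates, voom on the recovered reads, leaving out libraries with high hypoxia, low epicardial or high liver genes, the gene body with 5 kb, and strata of gene length and expression. Peaks and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.

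The fits were tested on simulated data with known changes. Each gene was drawn independently, with the same dispersion of 0.02 for every gene and both stages. At E9.5 (13627 genes) 50.8, 95.5 and 100% of genes changed by 1.5, 2 and 4-fold were called, and 5.82% of calls were false. At E10.5 (14080 genes) these were 20.9, 86.6 and 100%, and 6%. For the stage difference (13388 genes) they were 14.9, 67.2 and 100%, and 3.97%. In the data the median SD within groups was larger at E10.5 (0.231 against 0.152), and genes moved together between libraries. The simulated shares therefore check the fits and are not rates for these data.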

Results

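Polyadenylated RNA was sequenced from hearts of mouse embryos carrying unrecombined floxed Chd4 alleles (flox, the control) and from hearts in which both alleles were recombined and CHD4 was depleted (null). CHD4 is the chromatin-remodelling ATPase of the NuRD complex, which joins nucleosome remodelling to histone deacetylation. At embryonic day (E) 9.5 there were 5 flox and 5 null libraries, and at E10.5 there were 3 and 3, all described by the submitters as biological replicates. Depth at E9.5 was 19.6 to 23.5 M reads in flox and 17.1 to 20.1 M in null. At E10.5 it was 17.3 to 18 M in flox and 18 to 18.9 M in null. At these depths 1 RPKM of a 2 kb transcript was 34.1 to 47.0 reads, so differences of genes near 0.5 RPKM rested on few reads. No pair of libraries of a group held the same values, and pairs differed by more than sampling noise (chi-square per degree of freedom 9.63 to 59.5 at E9.5 and 16.1 to 95.4 at E10.5). CHD4 binding was mapped by chromatin immunoprecipitation in wild-type hearts at E10.0, in 3 libraries from 2 biological samples.

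Chd4 itself (chromosome 6, 125095980 to 125130591, mm10) was lower in every null library than in every flox library of its stage. At E9.5 the 5 flox libraries held 91.5, 92.3, 94.6, 91.2 and 92.7 RPKM and the 5 null libraries 48.8, 46.9, 45.4, 40.7 and 46.9 RPKM. The means were 92.5 ± 1.33 and 45.7 ± 3.08 RPKM (SD, n = 5 each), and Chd4 fell by 1.01 on the log2 scale (SE 0.0524, adjusted p = 1.69e-06). At E10.5 the flox libraries held 67.2, 74.6 and 91.1 RPKM and the null libraries 48.2, 57.4 and 52.5 RPKM. The log2 difference there was -0.55 (SE 0.161) and missed the threshold over all genes (limma adjusted p = 0.116). In the authors' deposited table Chd4 passed at both stages, with log2 ratios of control over null of 0.97 and 0.50. Which exons are removed is not given in the sources used here. The RPKM counts the whole gene, so these values include any transcript left from a recombined allele and from unrecombined cells.

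**Figure D1:**
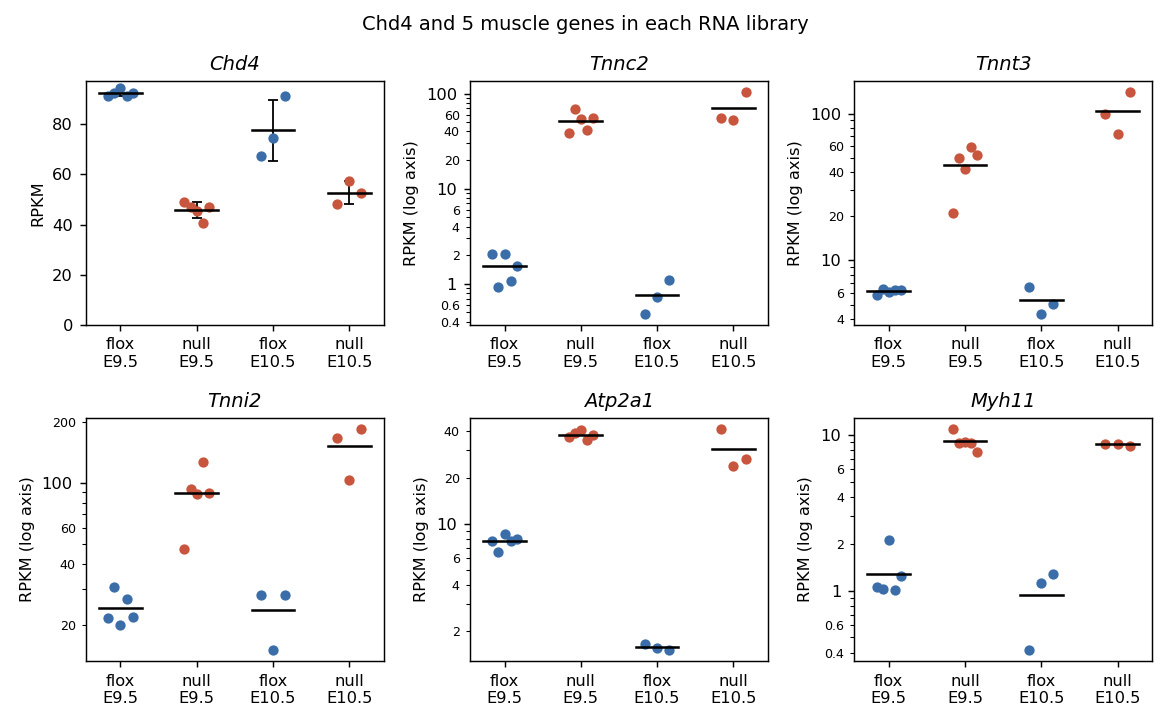
RPKM of Chd4 and of Tnnc2, Tnnt3, Tnni2, Atp2a1 and Myh11 in each library (points), by genotype and stage; horizontal lines are group means, and the bars on the Chd4 plot are SD. The y axis is linear for Chd4 and logarithmic for the 5 muscle genes, whose null libraries all lie above the flox libraries of the same stage.

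The question at E9.5 was which transcripts change in the heart when CHD4 is depleted. Among the largest changes were rises of some fast skeletal muscle genes. Tnnc2 (chromosome 2, 164777161 to 164779734), the fast skeletal troponin C, rose from 1.53 ± 0.529 to 51.5 ± 11.8 RPKM (SD, n = 5 each; log2 change 4.69, SE 0.198, adjusted p = 5.49e-07). Tnnt3, fast skeletal troponin T, rose from 6.16 ± 0.238 to 44.9 ± 14.8 RPKM (2.69, adjusted p = 6.18e-05). Myh11, the smooth muscle myosin heavy chain, rose from 1.29 ± 0.467 to 9.08 ± 1.16 RPKM (2.45, adjusted p = 5.47e-06). In the other direction, Nkx2-5, a homeodomain factor of the cardiac lineage, fell from 117 ± 19.1 to 42.9 ± 11.1 RPKM (-1.45, adjusted p = 0.000389). Gja5, which encodes the gap junction protein connexin 40, fell from 42.0 ± 7.67 to 17.2 ± 3.59 RPKM (-1.27, adjusted p = 0.000465).

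Other genes were higher at E9.5 in all 5 null than in all 5 flox libraries. Vil1, an actin-bundling protein of epithelial brush borders, rose from 1.59 ± 0.694 to 23.5 ± 4.18 RPKM (log2 change 3.58). Further rises were those of the helix-loop-helix factor gene Tcfl5 (1.11 ± 0.247 to 10.8 ± 1.97 RPKM, 2.80) and of Sypl2, a membrane protein of skeletal muscle triads (0.512 ± 0.0913 to 5.22 ± 1.14 RPKM, 2.48). Nkg7, a granule protein gene of cytotoxic lymphocytes, was read 0 to 2 times per flox library and 6 to 115 times per null library, and its call ended with the level of erythroid genes in the fit (log2 change 2.83, SE 0.482, before and 2.43, SE 0.662, after). Large falls were those of Tagln3 (10.8 ± 2.90 to 2.37 ± 0.729 RPKM, -1.97), Cend1 (10.6 ± 1.02 to 2.44 ± 0.414 RPKM, -1.92) and Slitrk5 (5.75 ± 1.44 to 1.59 ± 0.592 RPKM, -1.61), all 3 best known from neurons. Falls of like size were those of Fam189a2 (22.5 ± 2.49 to 5.99 ± 0.619 RPKM, -1.83) and Igfbpl1 (18.1 ± 2.94 to 5.64 ± 1.02 RPKM, -1.60). The adjusted p of these 9 genes ran from 1.69e-06 to 0.00330 (limma). The rule for named genes also returned Mir7045, which lies inside Chd4, Mir7037 and Mir7682. These microRNA loci of 57 to 64 bp held at most 7 reads in any E9.5 library, and no fold is given for them.

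Of 13643 genes tested at E9.5, 2342 changed (limma, adjusted p under 0.05, two-sided): 937 rose and 1405 fell, 188 and 39 of them by at least 2-fold. The 2 groups of libraries did not overlap for 14.1% of tested genes, where chance gives 0.794%. Rises made up 40.0% of the changed genes, and 51.3% when libraries were rescaled to a common median. Without null 5 the count was 1537, without the libraries with low epicardial genes it was 1349, with the sex of the library in the fit 1238, with the level of erythroid genes in the fit 379, and with arrayWeights 3549.

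The skeletal muscle sarcomere list moved up at E9.5. Of its 23 genes 14 were measured, at a mean of at least 0.5 RPKM. Among these 7 rose, 1 fell and 6 did not pass (8 and 1 adjusted over the list alone). Camera gave an adjusted p of 2.59e-05 (adjusted p = 0.111 with an estimated correlation). Fry gave an adjusted p of 8.97e-06. Atp2a1, the fast skeletal calcium pump of the sarcoplasmic reticulum, rose from 7.72 ± 0.752 to 37.9 ± 2.08 RPKM (log2 change 2.23, adjusted p = 5.42e-08). Tnni2, fast skeletal troponin I, rose from 24.2 ± 4.51 to 89.1 ± 28.5 RPKM (1.81, adjusted p = 0.000529). Acta1 (0.91), Ckm (0.49) and Tnnt1 (0.37) were other rises, and Casq1, the skeletal calsequestrin, was the fall (-0.40). These 4 were chosen after their values were seen. Among 12 smooth muscle contractile genes Myh11 was the 1 that rose and 11 did not pass (camera adjusted p = 0.192). Globin and other erythroid genes were higher in the same libraries, at 3.49 ± 1.43% of reads in null and 1.29 ± 0.511% in flox. With their level in the fit 5 skeletal muscle genes still rose.

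Part of the genes of the working heart muscle fell in the null hearts at E9.5. Of 25 measured cardiac sarcomere genes 11 fell and 14 did not pass (13 fell adjusted over the list alone; camera adjusted p = 2.59e-05; adjusted p = 0.447 with an estimated correlation). Tcap, the titin cap, fell from 33.3 ± 3.71 to 17.5 ± 3.18 RPKM (-0.92) and Xirp1 from 49.3 ± 4.07 to 32.3 ± 4.87 (-0.61). Csrp3 fell from 480 ± 32.5 to 343 ± 26.4 (-0.48), and Mybpc3, cardiac myosin binding protein C, from 351 ± 18.7 to 252.5 ± 26.8 (-0.48). The adjusted p of these 4 ran from 0.00115 to 0.00256. Among 15 genes of calcium handling and ion channels 8 fell (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00494; adjusted p = 0.410 with an estimated correlation). They included the potassium channel gene Kcnq1 (-0.42), junctophilin 2, Jph2 (-0.37), and the calcium channel gene Cacna1c (-0.28). Of 18 genes of mitochondrial energy metabolism 9 fell (12 adjusted over the list alone; camera adjusted p = 2.59e-05; adjusted p = 0.447 with an estimated correlation). Among them were Cpt1b (-0.68), Uqcrc1 (-0.37) and Cox4i1 (-0.32). The rise of erythroid genes accompanied these falls. With their level in the fit Tcap and Csrp3 were the 2 cardiac sarcomere genes that still fell. The calls of Xirp1 (log2 change -0.423, SE 0.0986 before and 0.111 after), Mybpc3 (-0.398, SE 0.0753 and 0.1004), Kcnq1 (-0.334, SE 0.101 and 0.138), Jph2 (-0.339, SE 0.0683 and 0.0971), Cacna1c (-0.201, SE 0.0659 and 0.0882) and Cox4i1 (-0.291, SE 0.04999 and 0.0689) ended. These 6 kept 0.690 to 0.926 of their change while the SE grew 1.12 to 1.42 times, so the lost calls do not show that blood accounts for the falls. After rescaling without erythroid and the top 10 genes 11 cardiac sarcomere genes fell and 86.7% of all E9.5 calls remained.

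Cardiac transcription factors fell at E9.5 in 9 of 18 genes, and 9 did not pass (10 fell adjusted over the list alone; camera adjusted p = 2.59e-05; adjusted p = 0.447 with an estimated correlation). Beside Nkx2-5, Hopx fell from 83.3 ± 5.00 to 37.3 ± 3.53 RPKM (log2 change -1.15, adjusted p = 5.48e-06) and Hand1 from 45.0 ± 7.78 to 22.2 ± 5.29 (-1.02, adjusted p = 0.00297). Hey1, a target of Notch signalling, fell from 34.7 ± 2.62 to 23.9 ± 0.902 (-0.53, adjusted p = 0.000278). The recombinase line is not named in the labels, so whether its allele alters 1 of these genes was not tested. In the chamber and trabecular list 4 of 16 genes fell (4 adjusted over the list alone; camera adjusted p = 0.499). They were Gja5, the neuregulin receptor genes Erbb2 (28.2 ± 1.78 to 18.4 ± 1.31 RPKM, -0.60) and Erbb4 (-0.30), and Cited1 (-0.79). The call of Erbb4 ended without any 1 of flox 1 to 5, null 3 or null 5 (adjusted p 0.0591 to 0.0848). With the level of erythroid genes in the fit Nkx2-5, Hopx, Hey1, Erbb2 and Gja5 kept their calls, and Hand1 (-1.05, SE 0.170 before and 0.243 after), Cited1 (-0.515, SE 0.141 and 0.156) and Erbb4 (-0.244, SE 0.0879 and 0.123) did not. The call of Erbb4 also ended after rescaling without erythroid and the top 10 genes (adjusted p = 0.0554).

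Markers of other cell types also differed at E9.5. Of 13 erythroid genes 9 rose (9 adjusted over the list alone; camera adjusted p = 8.80e-07; adjusted p = 0.447 with an estimated correlation). Among them were the transcription factor gene Gata1 (8.11 ± 2.90 to 19.3 ± 4.25 RPKM, log2 change 1.24), Slc4a1 (1.44) and the embryonic globin gene Hbb-bh1 (5097 ± 1919 to 14641 ± 5860 RPKM). In the list epicardium at E9.5 no gene passed in limma, at an unadjusted p under 0.05 or in voom (0 of 10 each). Camera put the list up (adjusted p = 0.0498; adjusted p = 0.791 with an estimated correlation). The list cushion mesenchyme and fibroblast at E9.5 was also up by camera (adjusted p = 0.0425; adjusted p = 0.734 with an estimated correlation). Of its 12 genes 0 passed in limma, 3 were higher at an unadjusted p under 0.05 and 1 rose in voom. The epicardial call ended without flox 1 (0.374), flox 3 (0.0780), null 2 (0.116), null 3 (0.103), null 4 (0.126) or null 5 (0.102). The cushion call ended without flox 1 (0.137), flox 3 (0.0573), flox 5 (0.0506), null 2 (0.0968), null 3 (0.0630), null 4 (0.0666) or null 5 (0.0662). Both calls also ended with no filter, under median scaling, quantile normalization and rescaling without erythroid and the top 10 genes, and with the sex or the erythroid level in the fit. Epicardial genes were low in flox 1 (mean log2 level 1.91), null 1 (2.50) and flox 3 (3.03), against 3.64 to 4.30 in the other E9.5 libraries. For the 15 endothelial and endocardial genes limma and voom called 0, with 1 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.889). For 6 foregut and liver genes limma, voom and the unadjusted p gave 0 (camera adjusted p = 0.889).

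**Figure D2:**
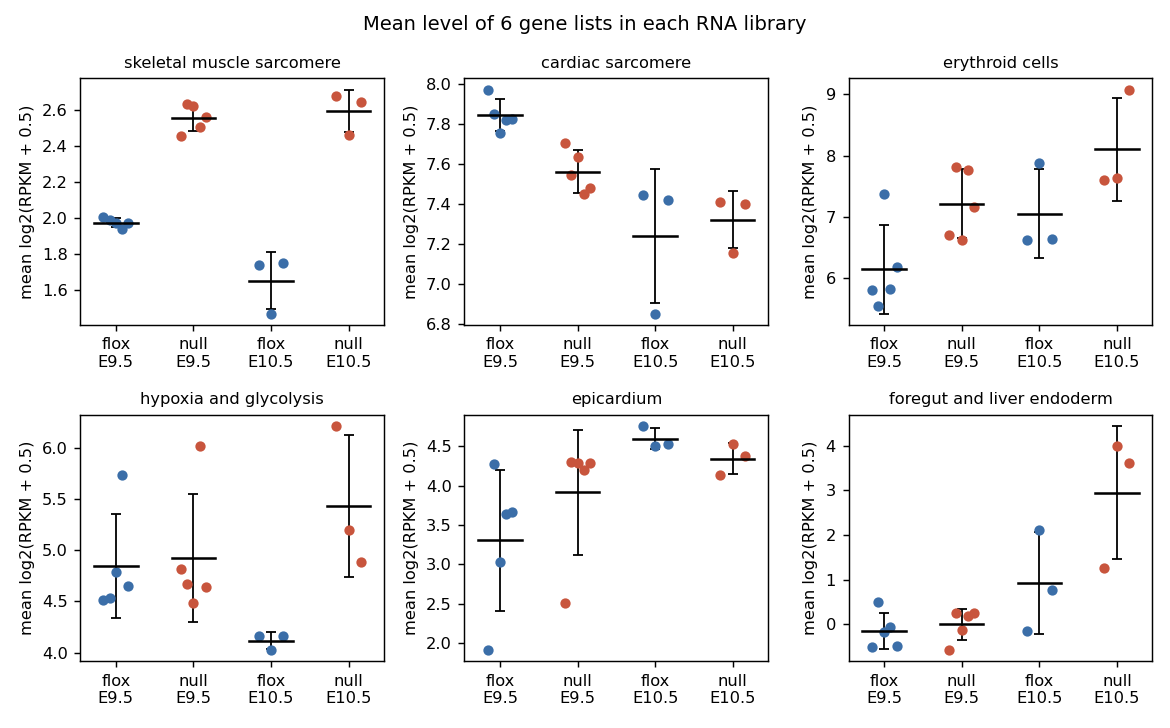
Mean log2(RPKM + 0.5) over the genes of 6 lists in each library (points), by genotype and stage; horizontal lines are group means and bars are SD (n = 5 per group at E9.5, 3 at E10.5). Skeletal muscle genes separate null from flox at both stages, and erythroid genes are higher on average in null libraries; 1 flox and 1 null library at E9.5 stand high for hypoxia genes and 3 E10.5 libraries stand high for foregut and liver genes.

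The balance between a non-cardiac contractile protein gene and its cardiac paralog was compared within each library for 12 pairs. This leaves out any scaling shared by the library, except for genes near the added 0.5 RPKM. At E9.5 the ratio was higher in every null than in every flox library for 9 pairs (exact permutation test, two-sided, p = 0.00794 each, the smallest that 5 against 5 allows, adjusted p = 0.0106). The log2 ratio rose by 4.89 for Tnnc2 over Tnnc1 (-9.42 ± 0.355 in flox, -4.54 ± 0.344 in null, n = 5 each), by 2.89 for Tnnt3 over Tnnt2, by 2.36 for Myh11 over Myh7, by 2.18 for Tnni2 over Tnni1 and by 1.26 for Acta1 over Actc1. Smaller rises of the ratio were those of Tnnt1 over Tnnt2 (0.58), Mybpc2 over Mybpc3 (0.40), Tpm2 over Tpm1 (0.37) and Acta2 over Actc1 (0.24). A ratio can also rise through a fall of the cardiac partner. Mybpc3 itself fell at E9.5 by more than the ratio of Mybpc2 to it rose. Tpm2 and Acta2 were not called as genes at E9.5. Groups overlapped for Mylpf over Myl7 (0.00046, exact p = 1), Myl9 over Myl7 (0.11, exact p = 0.476) and Myh3 over Myh7 (0.0032, exact p = 0.992). At E10.5 every null library lay above every flox library for 7 pairs. The differences were 5.86 for Tnnc2, 3.90 for Tnnt3, 2.60 for Tnni2, 2.23 for Acta1, 2.12 for Myh11, 1.15 for Tpm2 and 0.505 for Acta2, each over the same partner. Myl9 over Myl7 lay below in every null library (-0.39), and the other 4 pairs overlapped. With 3 against 3 the exact permutation p cannot go below 0.1, which these 8 pairs reached (adjusted p = 0.15). In the null libraries the skeletal and smooth muscle genes still gave fewer reads per kilobase than their partners, since all mean log2 ratios were below 0.

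**Figure D3:**
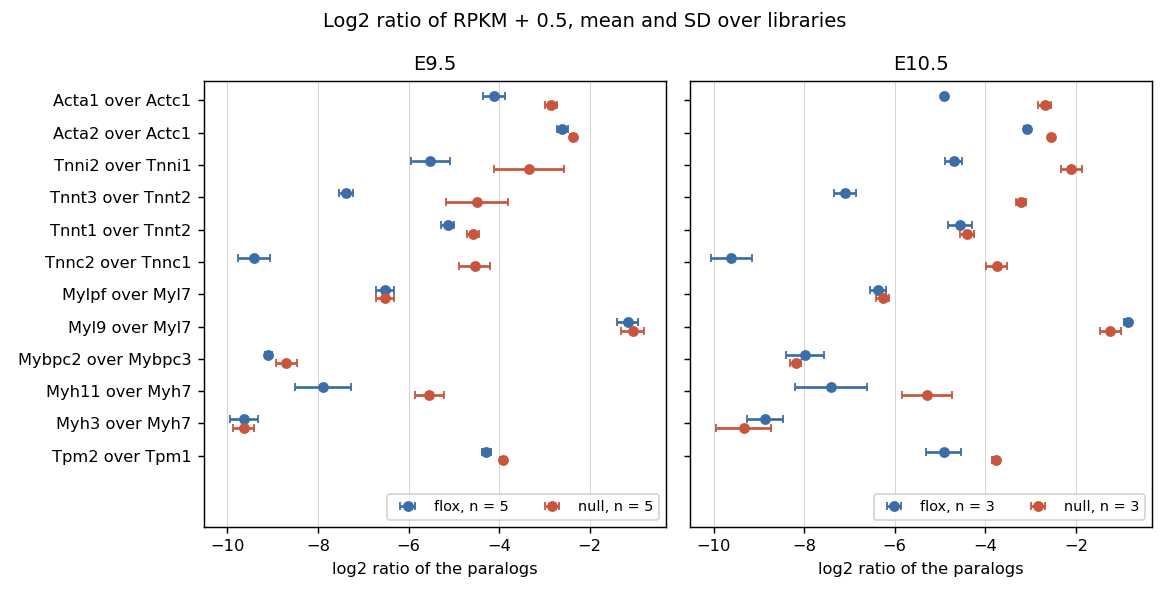
Log2 ratio of RPKM + 0.5 of 12 non-cardiac contractile protein genes over their cardiac paralogs, as group mean and SD over libraries (n = 5 per group at E9.5 and 3 at E10.5). The null means of Tnnc2, Tnnt3, Tnni2, Myh11 and Acta1 lie well to the right of the flox means at both stages.

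At E10.5 the same fast skeletal genes led the changes. Tnnc2 rose from 0.769 ± 0.305 to 70.6 ± 28.5 RPKM (SD, n = 3 each; log2 change 5.76, SE 0.288, adjusted p = 0.000171) and Tnnt3 from 5.34 ± 1.16 to 104 ± 34.1 (4.13, adjusted p = 0.000357). Atp2a1 rose from 1.57 ± 0.0812 to 30.6 ± 9.53 (3.87, adjusted p = 0.000288) and Tnni2 from 23.8 ± 7.63 to 151 ± 43.0 (2.66, adjusted p = 0.00601). Vil1 (0.314 ± 0.203 to 19.1 ± 2.13 RPKM, 4.61) rose again. Further large rises were those of Ndufa4l2 (0.824 ± 0.252 to 25.2 ± 19.4, 4.05) and Ndrg1 (2.42 ± 0.360 to 31.9 ± 29.3, 3.10), both induced by low oxygen, and of the peptide hormone gene Cck (3.43 ± 1.28 to 52.6 ± 14.6, 3.78). Null 1 was highest for Ndufa4l2 (47.7 RPKM, against 13.1 and 14.9 in null 2 and null 3) and Ndrg1 (65.6, against 17.9 and 12.3), and without it the log2 changes were 3.47 and 2.40 (adjusted p = 0.00132 and 0.00411). The heat shock gene Hspa1a stood at 3.67 RPKM in the same library and at most 0.314 in the other E10.5 libraries. Falls were led by Slitrk5 (6.99 ± 2.15 to 1.09 ± 0.158 RPKM), Gja5 (44.2 ± 5.20 to 9.76 ± 1.72, -2.13) and the homeodomain factor gene Alx4 (3.62 ± 1.72 to 0.391 ± 0.0724, -2.11). Igfbpl1 (16.2 ± 3.64 to 3.74 ± 0.834, -1.97), Tmem182 (3.35 ± 0.310 to 0.594 ± 0.414, -1.89) and Cend1 (7.79 ± 1.58 to 1.82 ± 0.105, -1.82) fell as well. These 14 genes had adjusted p from 0.000171 to 0.0272 (limma), and no null library overlapped a flox library for any of them. Mir7017 and Mir6917 also met the rule, at 61 and 60 bp and at most 8 reads in a library, and no fold is given for them.

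Of 14100 genes tested at E10.5, 292 changed: 249 rose and 43 fell, 210 and 29 by at least 2-fold. The groups did not overlap for 31.3% of genes, where chance gives 10%, with null above flox for 1955 genes and below for 2459. The count was 62 without flox 3, 63 without flox 1, 92 without flox 2 and 139 without null 2. With the sex of the library in the fit it was 79, with the erythroid level 63, with the epicardial level 21 and with the foregut and liver level 141. It was 162 with no filter and 1426 with arrayWeights (1033 rose and 393 fell). Leaving out the libraries with high liver genes (flox 2, null 2 and null 3) keeps 1 null library, so no count is given for that setting. The epicardial level ended the calls of Tnni2, Slitrk5, Cend1, Igfbpl1, Ndrg1, Alx4 and Tmem182 and not those of Tnnc2, Tnnt3, Atp2a1, Vil1, Ndufa4l2, Cck and Gja5. The 7 genes that lost their calls kept 0.718 to 0.968 of their log2 change, and the SE grew 1.11 to 1.44 times. Among the genes just named, the call of Alx4 ended without flox 1, flox 2, null 2 or null 3 (adjusted p 0.0555 to 0.104), that of Tmem182 without flox 1, flox 2 or flox 3 (0.0870 to 0.104), and that of Ndrg1 without flox 1, flox 2, flox 3 or null 2 (0.0592 to 0.103).

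By list, 6 of 14 skeletal muscle sarcomere genes rose at E10.5 and 8 did not pass (7 adjusted over the list alone; camera adjusted p = 2.35e-07; adjusted p = 0.730 with an estimated correlation). Beside the 4 above these were Acta1 (2.44) and Mybph (1.11), named after their values were seen. Fry gave the skeletal muscle list an adjusted p of 0.0367. Smooth muscle contractile genes were also up (3 of 12 rose, 4 adjusted over the list alone; camera adjusted p = 0.000953; adjusted p = 0.730 with an estimated correlation). Myh11 rose from 0.935 ± 0.459 to 8.70 ± 0.145 RPKM (2.74, adjusted p = 0.00306), a call that ended with the epicardial level in the fit (2.43, SE 0.260 before and 0.336 after). The enteric smooth muscle actin gene Actg2 rose from 2.90 ± 1.22 to 9.25 ± 1.87 (1.58) and Tpm2 from 22.4 ± 4.73 to 49.3 ± 6.70 (1.13). Actg2 at E10.5 was lost without flox 1, flox 2, flox 3, null 2 or null 3 (adjusted p 0.0794 to 0.0916). Tpm2 was lost without flox 1, flox 2, null 2 or null 3 (0.0542 to 0.116). In the same null libraries erythroid genes took 5.92 ± 3.59% of reads against 2.88 ± 1.93% in flox. There 5 skeletal muscle genes rose with the erythroid level in the fit and 3 with the epicardial level.

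Cardiac sarcomere genes gave no call at E10.5: 0 of 25 passed in limma (1 rose adjusted over the list alone), 2 were higher and 2 lower at an unadjusted p under 0.05, and voom called 1 rise (camera adjusted p = 0.543). Calcium handling and ion channels gave 0 of 15 in limma (1 fell adjusted over the list alone) and 0 in voom, with 1 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.405). Mitochondrial energy metabolism gave 0 of 18 in limma and voom and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.405). The list cardiac transcription factors at E10.5 was down by camera (adjusted p = 0.0419; adjusted p = 0.730 with an estimated correlation) and 0 of 18 genes passed in limma or voom, 1 adjusted over the list alone and 3 at an unadjusted p under 0.05. Hopx was at 82.5 ± 25.4 in flox and 38.9 ± 4.98 RPKM in null (adjusted p = 0.0755), and Nkx2-5 at 38.5 ± 13.1 and 24.0 ± 1.62 (adjusted p = 0.205). Flox 2 held 23.6 RPKM of Nkx2-5, within the null range of 22.2 to 25.2, and flox 1 and flox 3 held 48.1 and 43.7. Without flox 2 the number of cardiac sarcomere genes that fell was still 0. The camera call of cardiac transcription factors ended without flox 1 (0.118), flox 3 (0.0674), null 2 (0.0995) or null 3 (0.353). It also ended with the foregut and liver level in the fit, where the list changed sign (0.918), and with the erythroid level (0.941) or the sex (0.0903). It ended too under quantile normalization (0.121) and at a mean of at least 1 RPKM (0.0538). In the chamber and trabecular list Gja5 fell and Nppb, which encodes B-type natriuretic peptide, rose from 146 ± 47.9 to 394 ± 64.8 RPKM (1.47), with 14 of 16 not passing (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.632). Nppb was lost without flox 2, flox 3, null 1, null 2 or null 3 (adjusted p 0.0571 to 0.108).

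Hypoxia and glycolysis genes were higher in all 3 null libraries at E10.5 (mean log2 levels 6.21, 5.19 and 4.88, against 4.16, 4.02 and 4.17 in flox). Of 16 genes 1 passed over all genes, Ndrg1, and 15 adjusted over the list alone (camera adjusted p = 3.81e-10; adjusted p = 0.730 with an estimated correlation). At E9.5 the same list gave 0 of 16 in limma, in voom and at an unadjusted p under 0.05 (camera adjusted p = 0.749), with flox 4 at 5.74 and null 4 at 6.02 and the other 8 libraries between 4.48 and 4.81.

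Other cell types differed between E10.5 libraries as well. Foregut and liver genes were up by camera (adjusted p = 0.00206; adjusted p = 0.730 with an estimated correlation) with 0 of 11 passing in limma or voom and 4 at an unadjusted p under 0.05. Afp, the fetal serum protein of liver, was at 865 RPKM in null 2, 728 in null 3, 12 in null 1, 148 in flox 2, 1.42 in flox 1 and 0.975 in flox 3, so that flox 2 stood above null 1. The call of this list ended with the erythroid level in the fit (0.126). Of 13 erythroid genes Hbb-bs rose (63.0 ± 16.3 to 292 ± 172 RPKM, log2 change 2.09; 3 rose adjusted over the list alone; camera adjusted p = 0.000706; adjusted p = 0.730 with an estimated correlation). Beside Hbb-bs, the 3 adjusted over the list alone were Hba-a1 and Hba-a2. These held the same reads in every E10.5 library, so they are 1 measurement. The call of Hbb-bs ended without flox 1, flox 2, flox 3 or null 2 (adjusted p 0.0618 to 0.135), and that of the list with the foregut and liver level in the fit (0.412). Macrophage and platelet genes were up by camera (adjusted p = 0.0149; adjusted p = 0.730 with an estimated correlation) with 0 of 11 passing in limma or voom and 3 at an unadjusted p under 0.05. Without null 3 the adjusted p was 0.190, with the sex in the fit 0.0903, with the erythroid level 0.941 and with the foregut and liver level 0.9145. Among 12 cushion and fibroblast genes Col1a1 rose from 23.4 ± 4.32 to 49.9 ± 2.81 RPKM (1.09; camera adjusted p = 0.632). It was lost without flox 1, flox 3 or null 2 (adjusted p 0.0544 to 0.0885). Among 15 endothelial genes Egfl7 rose from 26.2 ± 3.61 to 49.6 ± 5.47 RPKM (0.91; camera adjusted p = 0.774). It was lost without flox 1, flox 2, flox 3, null 2 or null 3 (adjusted p 0.0539 to 0.149). In both lists that gene was also the 1 adjusted over the list alone. For 10 epicardial genes limma and voom called 0, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.153).

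Whether the effect of CHD4 depletion differed between the stages was tested as an interaction over the 13418 genes tested at both. Log2 changes at the 2 stages correlated across genes (Pearson 0.46, Spearman 0.28; genes are not independent replicates, so no p is given). Of genes that rose, 145 were called at both stages out of 911 and 239, where independent lists share 16.2 (Fisher's exact test, one-sided, p = 3.64e-109). Of genes that fell 26 were shared out of 1392 and 41, where independent lists share 4.25 (exact p = 2.83e-16). Both tests treat genes as independent, which they are not, so these p values do not measure repeatability between embryos. Of 280 genes called at E10.5 and tested at both, 257 had the same sign at E9.5, and 1 was called in opposite directions. Among the named genes the rise was larger at E10.5 for Atp2a1 (log2 difference 1.64, adjusted p = 0.00399), Tnnt3 (1.44, adjusted p = 0.0452) and Cck (2.51, adjusted p = 0.0234). Tnnc2 did not pass this test (1.08, adjusted p = 0.0859), nor did Chd4 (0.46, adjusted p = 0.0545). Kif5c, a neuronal kinesin gene, went the other way (difference -1.40, adjusted p = 0.0235), rising at E9.5 (1.13 ± 0.189 to 3.82 ± 0.776 RPKM, n = 5 each) and standing at 2.35 ± 0.287 and 2.43 ± 0.898 RPKM at E10.5 (n = 3 each). By camera the stages differed for hypoxia (adjusted p = 1.14e-05), cardiac sarcomere (0.000975), skeletal muscle sarcomere (0.000975), smooth muscle (0.0157) and foregut genes (0.0157), each higher at E10.5 relative to E9.5. With an estimated correlation the adjusted p was 0.901, 0.901, 0.789, 0.789 and 0.901.

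Across all genes 542 differed between stages (352 with a higher change at E10.5, 190 lower), and this count rested on few libraries. It was 0 by limma without the E9.5 libraries with low epicardial genes (2671 at an unadjusted p under 0.05, smallest adjusted p 0.0854), so the calls of Atp2a1, Tnnt3, Cck and Kif5c ended there. With the epicardial level in the fit 42 genes were called, these 4 among them (adjusted p 0.0208 to 0.0493). The count was 184 without the libraries with high hypoxia genes, 234 with arrayWeights and 831 with quantile normalization. Among E10.5 libraries it was 4 without flox 1, 9 without flox 2, 975 without flox 3, 1796 without null 2 and 313 without null 3. Among E9.5 libraries it was 117, 175, 145 and 117 without flox 1, 2, 3 and 4 and 60, 841 and 20 without null 3, 4 and 5. The calls of Cck and Kif5c ended without null 5 of E9.5 or without flox 1 or flox 2 of E10.5 (adjusted p 0.0528 to 0.0623 for Cck). That of Kif5c ended also without null 3 of E9.5 (0.0501 to 0.0623) and with the foregut and liver level (0.0515), and that of Cck with arrayWeights (0.0586). The call of Tnnt3 ended without any 1 of 12 libraries (0.0543 to 0.105), and with no filter, arrayWeights, robust eBayes, voom or the foregut and liver level (0.0512 to 0.0903). It ended too without the libraries with high hypoxia genes (0.0543). No single library ended that of Atp2a1. Libraries of the 2 stages also differed in the RNA put in, 200 ng at E9.5 and 300 ng at E10.5.

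The fits above were compared with the comparison lists the authors made. The authors' deposited table for E9.5 lists 3094 genes, 1625 higher and 1469 lower in null hearts. Of these, 2149 (69.5%) were also called here, and 2790 of the 2793 that were tested here had the same direction. For E10.5 the authors' deposited table lists 1357 genes, 932 higher and 425 lower. Of these, 276 (20.3%) were called here, and 1280 of 1281 tested had the same direction. At an adjusted p under 0.1 here the E10.5 share was 52.3%. The authors' deposited table also lists Chd4, Tnnc2, Tnnt3, Atp2a1 and Gja5 at both stages. Called here but not listed there were 193 genes at E9.5 and 16 at E10.5.

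CHD4 binding at E10.0 was described by 84271, 60749 and 50232 peaks in the 3 libraries, with median widths of 211, 185 and 180 bp. Pairs of lists shared 35.3 to 64.7% of their peaks by at least 1 bp, against 1.56 to 3.09% after moving a list by 1 Mb. Peaks found in all 3 numbered 22824 in the first list (27.1%), 23812 in the second (39.2%) and 24406 in the third (48.6%). Without replicate 3 the first list shared 35374 with the second. The shared peaks had higher scores than the rest, where the score is the authors' own value (median 83 against 32, 62 against 30 and 53 against 30). Of the 5 highest shared peaks of the first list 3 lay at chromosome 2, 98666576 to 98667307 (score 9919, no annotated gene), in the mitochondrial genome, 14121 to 15798 (4768), and at chromosome 11, 101657501 to 101660373 (4600, over the small nuclear RNA gene Rnu2-10). The others lay at chromosome 9, 35305247 to 35305577 (4234, over Gm33838), and chromosome 2, 98662243 to 98662959 (3727, no annotated gene). Mitochondrial and repeated sequence is known to give high signal in such assays, and the input libraries were not analysed here.

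The study asks whether CHD4 acts on the changed genes directly, so shared peaks were counted within 5 kb of either annotated end of each gene. Genes that rose at E9.5 had such a peak less often than genes with no call: 51.0% (477 of 935) against 67.5% of 11263 (odds ratio 0.502, 95% interval 0.438 to 0.575, Fisher's exact test, two-sided, p = 1.95e-23, adjusted p = 7.80e-23). Genes that fell at E9.5 had one more often, 76.3% (1070 of 1403; odds ratio 1.55, 1.36 to 1.77, exact p = 9.80e-12, adjusted p = 1.96e-11). At E10.5 both were below the 65.7% of the 13766 genes with no call, at 54.6% of 249 genes that rose (odds ratio 0.627, 0.484 to 0.814, adjusted exact p = 0.000460) and 46.5% of 43 that fell (0.453, 0.236 to 0.864, exact p = 0.00988). Within quintiles of mean expression over flox and null libraries the odds ratios were 0.566, 1.33, 0.703 and 0.479, in the same order. This mean includes the null level, which the change itself moves, while binding was mapped in wild-type hearts. The quintiles therefore do not hold the level in control hearts fixed, and a part of it in these differences is not excluded. The p values of these tests also treat genes as independent. With a 50 kb window the odds ratio of genes that rose at E10.5 was 0.977 (exact p = 0.852). For genes that fell at E10.5 it was 0.45 (Fisher's exact p = 0.0391, adjusted p = 0.0522). With peaks of the first list alone the odds ratio of these fallen genes was 0.445 (95% interval 0.208 to 1.06).

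Among skeletal and smooth muscle genes called at either stage, shared peaks near an end were found at Acta1 (chromosome 8, 123891432 to 123891674, outside the gene, score 32), Tnnt1 (3 peaks), Casq1 (3), Ckm (2), Tpm2 (4) and Tnnc2. The Tnnc2 peak, at chromosome 2, 164784320 to 164784472, outside the gene, had a score of 19. At Tnni2, Tnnt3, Mybph, Atp2a1 and Actg2 no shared peak lay within 5 kb of an end or in the gene, and Myh11 held 2 in its body and none near an end. Shared peaks are 27.1% of the first list. Peaks held by fewer lists were not looked up at these genes, so binding there is not excluded.

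**Figure D4:**
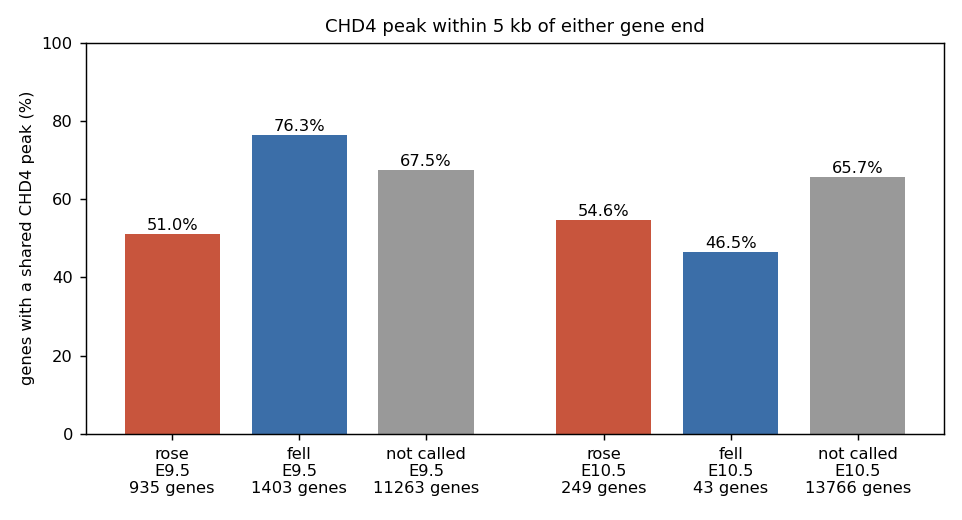
Percent of genes with a CHD4 peak of all 3 libraries within 5 kb of either annotated gene end, for genes that rose, fell or were not called at each stage (bars from 0; gene numbers under each bar). At E9.5 genes that fell have a peak most often (76.3%) and genes that rose least often (51.0%).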

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

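The test of liver bud markers was chosen after the result was seen, and so were the sex test's covariate, the use of risen members alone, the reading of each stage apart, the margins of error around the bounds and the rule that the number of libraries is excluded only if under 5% of subsets call as few genes; a condition on the level of the somite markers was tried and dropped after their values were seen. The other tests were chosen before.

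Of 14 measured skeletal muscle sarcomere genes (23 listed) 7 rose and 1 fell in null hearts at E9.5 and 6 rose at E10.5. Camera gave adjusted p = 0.111 and 0.730 with an estimated correlation. Fry gave adjusted p = 8.97e-06 at E9.5 and 0.0367 at E10.5. For the rises 3 technical explanations were tested. The ratio of fast skeletal Mylpf over Myl7 overlapped between groups at both stages. Somite or myoblast tissue carried into null libraries would bring Myf5, Myod1, Myog and related markers along, but their median log2 change was 0.0006 at E9.5 (-0.141 to 0.296 over 10 markers) and -0.246 at E10.5 (-1.2 to 0.249), which argues against it. At E9.5 8 of the 10 stayed under 0.5 RPKM in every library, so that median rests on low genes, but Myog was at most 0.0687 RPKM in null libraries whose Tnnc2 averaged 51.5 RPKM. With the sex of the library in the fit the median change of the risen genes kept 0.928 of its size at E9.5 and 0.992 at E10.5, and after rescaling without erythroid and the 10 most abundant genes 1.02 and 1.01, which argues against both as the whole cause. With the epicardial level in the fit 8 of the 14 rose at E9.5 and 3 at E10.5. A candidate explanation that remains is that loss of CHD4 raises these genes within heart cells, a hypothesis found on these data that no test here addressed. The driver allele, litter and the shares of other heart cell types were not tested.

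Fewer genes were called at E10.5 (292) than at E9.5 (2342). Subsets of 3 against 3 libraries of E9.5 called a median of 591.5 genes (52 to 2719), 2.03 times the E10.5 count. Fewer libraries thus lowered the E9.5 count from 2342 to that median, so the number of libraries accounts for part of the difference. The median passes the bound of 1.5 set before, which counts against the number of libraries as the whole cause. It does not pass by more than the spread, since 32 of 100 subsets called no more than 292. Whether the number of libraries is the whole cause stays open. The spread within groups was 1.52 times larger at E10.5 (median SD 0.231 against 0.152), with null at 0.262 and flox at 0.153, which is consistent with spread between libraries as a part of it. No biological explanation was tested.

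Foregut and liver genes stood high in 3 of the 6 E10.5 libraries. Of 12 liver bud markers outside the list in which this was seen, 83.3% had flox 2, null 2 and null 3 each above flox 1, flox 3 and null 1. A candidate explanation is liver bud tissue carried along in flox 2, null 2 and null 3, in which Afp reached 148, 865 and 728 RPKM and Alb 12.2, 361 and 83.4 RPKM. No biological explanation was tested.

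Other splits of the libraries show where chance can be excluded. At E9.5 1 of 100 splits, the real one, called as many genes (2342, highest other 2), so chance can be excluded for the gene count, but 17 of 100 gave as many lists (8, highest other 10), so it cannot for the count of lists. At E10.5 there are 10 splits, too few for a share under 0.05. The real one called 292 genes (highest other 6, 1 of 10 as large) and 7 lists (highest other 12, 6 of 10 as large). The other splits called a median of 5 lists at E9.5 (93 of them called some) and of 7 at E10.5 (9 called some). Camera with the preset correlation thus called lists under most groupings of the libraries. Its adjusted p of a list does not by itself show an effect of genotype. For the stage difference 3 of 100 splits gave as many genes as the real 542 (highest other 1938).

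Single libraries stood apart from their group at E9.5 for 49 of 370 values tested, where chance flags about 1 in 20 groups (18.5 here). The values given are the gap to the nearest library over the range of the group, against a critical value of 0.71. In flox 5, the male library of its group, Xist was lowest (0.975) and Ddx3y (0.903), Kdm5d (0.966), Uty (0.94), Eif2s3y (0.823) and the sex-linked list (0.838) were highest. In flox 4 hypoxia genes were highest, with P4ha1 at 0.752, Ndufa4l2 at 0.863, Ndrg1 at 0.721, Egln3 at 0.805 and the list at 0.779. Tfap2a was also highest there (0.723), and Tcap (0.715) and Cycs (0.752) lowest. In null 4 the same genes were highest (P4ha1 0.852, Ndufa4l2 0.812, Ndrg1 0.898, Egln3 0.895, the list 0.785), with Rbbp7 (0.789), Tmem38a (0.804) and Atf3 (0.76). Slitrk5 (0.714), Hopx (0.733), Tbx20 (0.76), Has2 (0.732) and Msx1 (0.722) were lowest in null 4.

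In null 1 epicardial genes were lowest, with Aldh1a2 at 0.792, Sema3d at 0.86, Upk3b at 0.888, Aldh1a1 at 0.833, Lrrn4 at 0.729, Bnc1 at 0.813, Tbx18 at 0.718 and the list at 0.937. Nkg7 (0.766), Emcn (0.853), Col3a1 (0.721), Col1a2 (0.722), Fcgr3 (0.717) and Pln (0.752) were lowest there too, and Tbx18 (0.817) was lowest in flox 1. In flox 3 Myh11 (0.754), Hbb-bs (0.732), Hba-a1 (0.748), Hba-a2 (0.748) and the percent of reads in the top 10 genes (0.761) were highest. In flox 2 the liver genes Alb (1) and Afp (0.763) were highest, at 1.77 and 24.8 RPKM.

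The genotype effect differed between stages, by the interaction test, for 16 of the genes named by the rule. The effect at E10.5 minus that at E9.5 was 1.64 for Atp2a1, 1.44 for Tnnt3, 0.981 for Tpm2, 0.837 for Wnt11, 0.783 for Egfl7, 1.07 for Aldoa, 1.23 for Eno1, 2.51 for Cck, 2.41 for Tuba1c, 2.33 for Mir6945 and 1.99 for Mir410. These 2 microRNA loci of 67 and 80 bp held 2 to 13 and 1 to 16 reads per E10.5 library, so their values rest on few reads and are not read as folds. It was -1.4 for Kif5c, -1.28 for Neto2, -1.06 for Lix1, -1.05 for Mob1a and -0.368 for Hdac2. By camera it differed for hypoxia and glycolysis (median difference 1.2), cardiac sarcomere (0.435), skeletal muscle sarcomere (0.576), smooth muscle (0.415) and foregut and liver genes (3.42). With an estimated correlation none of these 5 lists was called (adjusted p 0.901, 0.901, 0.789, 0.789 and 0.901). Of the 8 chosen for the size of the difference, single libraries ended each call: Cck and Neto2 3 libraries each (adjusted p 0.0528 to 0.0623), Kif5c 4 (0.0501 to 0.0623), Mir6945 1 (0.0551), Tuba1c 6 (0.0539 to 0.0847), Mob1a 7 (0.0504 to 0.0771), Mir410 7 (0.0536 to 0.0766) and Lix1 10 (0.0531 to 0.103). Of the others, no single library ended the call of Atp2a1, and those of Hdac2 (13 libraries, 0.0563 to 0.111), Tnnt3 (12, 0.0543 to 0.105), Aldoa (12, 0.0526 to 0.0999), Wnt11 (10, 0.0535 to 0.1), Egfl7 (8, 0.0602 to 0.107), Eno1 (4, 0.0505 to 0.0771) and Tpm2 (2, 0.0551 to 0.0623) ended.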

How the results depend on the processing

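The sex, cell type and subset settings and voom were chosen after the data were seen, the rest before. At E9.5 (2342 genes) the count was 3549 with arrayWeights, 1238 with sex, 379 with the erythroid level, 1349 without the low-epicardium libraries, and 1537 to 2773 leaving out 1 library. The lists called (8) were 0 by camera with an estimated correlation (2 at an unadjusted p under 0.05, smallest adjusted p 0.111). Fry called 5, the cardiac and skeletal muscle sarcomere, calcium handling, cardiac transcription factor and mitochondrial lists. Leaving out 1 library gave 6 to 8 lists. At E10.5 (292) the count was 162 with no filter, where more genes are tested, 1426 with arrayWeights, 79 with sex, 63 with the erythroid, 21 with the epicardial and 141 with the foregut and liver level. It was 541 without the high-liver libraries, which leaves 1 null library, assumed to vary like the others, and 62 to 356 leaving out 1 library. The lists called at E10.5 (7) were 4 with the erythroid level (3 of the 7 and 1 other), 11 without the high-liver libraries (5 of the 7 and 6 others), 0 with an estimated correlation (0 at an unadjusted p under 0.05, smallest adjusted p 0.730) and 1 by fry; leaving out 1 gave 5 to 8. The list erythroid cells at E10.5 changed sign with the erythroid level (0.941), which is its own mean, so the fit fixes that outcome and it says nothing of the list. The list cardiac transcription factors at E10.5 changed sign with the foregut and liver level (0.918). Neither was called. The stage difference (542) was 831 with quantile normalization, 234 with arrayWeights, 42 with the epicardial level, 184 without the high-hypoxia libraries, 1641 without the high-liver ones, 4 to 1796 leaving out 1, and 0 by limma without the low-epicardium libraries (2671 at an unadjusted p under 0.05, smallest adjusted p 0.0854). The authors' E10.5 lists overlapped by 52.3% at an adjusted p under 0.1, peaks in all lists were 27708 to 35374 leaving out 1, and the 50 kb odds ratio of genes that rose at E10.5 was 0.977. Paralog ratios leaving out 1 numbered 9 to 9 at E9.5 and 8 to 9 at E10.5. The E10.5 numbers are pairs whose groups did not overlap, in either direction. None of them is a call, since 3 against 3 cannot reach an adjusted p under 0.05. Apart from fewer libraries and genes the cause was not tested.

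Some skeletal muscle genes rose in every setting that kept more than 1 library per group, 5 to 8 at E9.5 and 3 to 6 at E10.5. Of the 23 listed, 14 were measured in the main fit, and settings with another filter measure other numbers. Over all settings 960 values of lists kept their side of the threshold, 48 became weaker, 18 stronger and 2 reversed. For named genes these were 2605, 116, 69 and none at E9.5, 2045, 123, 67 and none at E10.5, and 205, 67 and none for the stage difference. Depth limits genes near 0.5 RPKM.

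With the replicate number as a block the counts were 3698 genes at E9.5, 269 at E10.5 and 1384 for the stage difference, and exact sign flips of the paralog ratios gave 0 at E9.5, where 5 pairs cannot go below p = 0.0625 (adjusted p 0.0833, 0 at an unadjusted p under 0.05); 3 pairs at E10.5 gave no value. Same-numbered libraries correlated at 0.451, 0.0417, -0.136, 0.519 and 0.258 at E9.5 and 0.0509, 0.106 and -0.0299 at E10.5, and 3 of 5 and 2 of 3 matched their own number best, where chance gives about 1 each. The mean at E9.5 (0.227) was reached by 3 of 120 matchings (exact p = 0.025, one-sided, n = 5 pairs, chosen after the data were seen) and that at E10.5 (0.0424) by 3 of 6. Hypoxia genes were highest in flox 4 and null 4 (mean log2 level 5.74 and 6.02) and epicardial genes lowest in flox 1 and null 1 (1.91 and 2.50). This hints at something shared by same-numbered E9.5 libraries, which the labels do not state, so the main analysis stayed unpaired as planned.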

Other observations

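Some lists fixed before the data were examined enter no comparison above. CHD4 shares its place in NuRD with related ATPases, and of 13 other NuRD subunits Chd3 rose at E9.5 (14.8 ± 0.75 to 26.3 ± 2.61 RPKM, SD, n = 5 each; log2 change 0.81, limma adjusted p = 7.39e-05). Mta1 fell there (-0.30), and its call ended without any 1 of flox 3, 4 or 5 or null 2, 3 or 5 (adjusted p 0.0523 to 0.0667). At E10.5 limma and voom called 0 of 13, with 2 higher and 1 lower at an unadjusted p under 0.05. Camera gave adjusted p of 0.904 and 0.632. In the second heart field Wnt11 fell at E9.5 (13.8 ± 2.08 to 8.27 ± 1.68 RPKM, -0.71), and 6 of 7 did not pass (camera adjusted p = 0.882). At E10.5 limma and voom called 0 of 8, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.697).

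Cell division genes Top2a (0.22), Mki67 (0.49) and Ccna2 (0.18) rose at E9.5 and 16 of 19 did not pass (camera adjusted p = 0.227). At E10.5 limma and voom called 0 of 19, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.632). Of 13 p53 targets at E9.5 Eda2r (0.93), Pmaip1 (0.79) and Cdkn1a (0.69) rose and Perp fell (-0.66; camera adjusted p = 0.309), and at E10.5 1 of 14, Cdkn1a, rose (8.39 ± 1.64 to 23.9 ± 9.49 RPKM, n = 3 each, 1.41; camera adjusted p = 0.213). Of 8 immediate early and heat shock genes Junb rose at E9.5 (0.83; camera adjusted p = 0.889), and at E10.5 limma and voom called 0 of 9, with 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.153).

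Of 7 macrophage and platelet genes at E9.5 Fcgr3 rose (1.39) and Lyz2 fell (-0.64; camera adjusted p = 0.309). Of 5 neural genes Nefl fell (3.41 ± 0.606 to 1.68 ± 0.319 RPKM, -0.84; camera adjusted p = 0.766), and at E10.5 limma and voom called 0 of 6, with 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.405). The 5 sex-linked genes gave 0 in limma, voom and at an unadjusted p under 0.05 at both stages (camera adjusted p = 0.309 and 0.580); by Xist against Ddx3y flox and null held 4 and 2 female libraries of 5 at E9.5 and 2 and 1 of 3 at E10.5. Single libraries ended the E9.5 calls of Ccna2 (flox 2, 3, 4 or 5, null 3 or 5; adjusted p 0.0558 to 0.0680), Pmaip1 (flox 1, 3 or 5, null 2; 0.0522 to 0.0663) and Cdkn1a (flox 1, 2, 3 or 5, null 2 to 5; 0.0622 to 0.110). They also ended those of Junb (flox 1, 2, 3 or 5, null 2 to 5; 0.0630 to 0.111) and Lyz2 (flox 1, 2, 3 or 5, null 1, 4 or 5; 0.0541 to 0.0906), and the E10.5 call of Cdkn1a (flox 1 to 3, null 2 or 3; 0.0542 to 0.142).

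Adjusted over the list alone, the genes that rose and fell at E9.5 numbered 1 and 1 for NuRD, 1 and 2 for the second heart field, 3 and 0 for cell division, 3 and 1 for p53 targets, 1 and 1 for immediate early genes, 1 and 1 for macrophages and 0 and 1 for neural genes. At E10.5 1 p53 target and 1 immediate early gene rose and 1 neural gene fell. With the erythroid level in the fit the E9.5 calls of Wnt11, Top2a, Mki67, Ccna2, Eda2r, Pmaip1, Cdkn1a, Junb, Fcgr3, Lyz2, Nefl and Mta1 ended, and those of Chd3 and Perp did not. The 12 kept 0.428 (Junb) to 1.12 times (Mta1) their log2 change, and the SE grew 1.15 to 1.43 times.

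Median, mean and camera direction of a list differed in sign at E9.5 for NuRD (median -0.05, mean -0.01, up), endothelium (-0.04, -0.02, up), neural (0.26, -0.0029, up), foregut and liver (-0.13, 0.18, up), hypoxia (-0.01, 0.08, up) and immediate early genes (-0.10, 0.07, up), and at E10.5 for endothelium (-0.01, 0.04, up).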
